A study of Mus musculus with 4 samples.

How the data were processed

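Expression was measured on Affymetrix Mouse Exon 1.0 ST arrays in 4 samples of mouse bladder epithelial cells in culture: 2 from p63 knockout newborns and 2 from wild-type newborns. Per the labels' protocols, RNA was isolated with column kits for small and standard inputs and labelled with biotin, and each sample went to 1 array. The deposited table holds log2 intensities, 1 value for each of 23332 transcript clusters (the array's gene-level probe groups) on each array, with no missing values. The log2 scale was read from the values: they run from 0.79 to 13.9, which as log2 fits a scanner's intensity range. Per the submitters' processing notes, Affymetrix Expression Console and Partek were used and the build was mm9. Their versions, the summarisation method and the normalization between arrays are not given in the sources used here. Array scanner files, probe-level values and detection calls were not used here. Array medians lay between 5.08 and 5.13, but the lower quartiles were 4.06 and 4.06 in the knockout arrays and 3.80 and 3.82 in the wild-type arrays. An authors' step that equalised whole gene-level distributions is therefore not visible in the table. No sample was pooled, and no column of other samples was present.

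Gene names came from GEO's platform annotation. It gave 1 gene symbol to 14996 clusters and several symbols to 1019 clusters, and listed none for 7317. Entrez identifiers of 14941 clusters matched a RefSeq table of assembly GRCm38, and the match changed 0 symbols. Clusters with several symbols or none were tested but never named. The build named by the submitters differs from that of the table, so no coordinates are given, and chromosomes were used only to tell sex-linked from autosomal genes. Where a gene had more than 1 cluster (135 genes), the cluster with the highest mean over the 4 arrays stood for it in gene lists.

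The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 4 arrays, no covariates, no filter on dim clusters) on the log2 values as deposited. Calls are clusters with a Benjamini-Hochberg adjusted p under 0.05 over all 23332 clusters. With 2 arrays per group the fit had 2 residual degrees of freedom and 2.2 prior ones. A total of 34 gene lists, with the members fixed before the data were examined, were compared with all other genes by limma's camera test at a preset inter-gene correlation of 0.01, over 14860 genes. The 32 lists with at least 3 measured members were tested and adjusted together. The lists covered basal, superficial and general epithelial markers, known p63 targets, hemidesmosomes and basement membrane, desmosomes, squamous and columnar genes, and markers of fibroblasts and feeder cells, smooth muscle, endothelium, leukocytes, neurons and Schwann cells and erythroid cells. Others covered the cell cycle, cell cycle inhibitors, p53 targets, the Notch, Wnt, Hedgehog and growth factor pathways, epithelial to mesenchymal transition, interferon, inflammation, tight junctions, cholesterol synthesis, glycolysis, retinoic acid and xenobiotic metabolism, and urogenital transcription factors. The last lists were sex-linked genes, chromosomal neighbours of Trp63, the p53 family, ribosomal proteins and stress genes. Each list was also tested with the correlation estimated from the residuals. Values are means ± SD of log2 intensity, and a fold is 2 to the power of the difference in log2 means.

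The named genes were Trp63, the 12 largest increases and 12 largest decreases among calls with 1 gene symbol and no overlap between groups, up to 6 calls of each fixed list, up to 3 members of lists with no call, the most abundant members of the lists of other cell types, and all measured sex-linked genes and neighbours of Trp63. Genes named outside this rule are marked as such. The files carry no background flags. As a guide to the level of silent genes, the 95th percentile of the 719 olfactory receptor clusters over all arrays was 5.08, a choice made after the data were seen. It lay close to the median of all clusters on each array (5.08 to 5.13), while the olfactory receptor medians were 2.80 to 3.35. A mean at or below 5.08 therefore does not by itself mark a gene as silent. A fold against a group mean at or below that level is open to understatement.

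The fit was tested on simulated data for this comparison (10 runs on 23332 clusters, 200 of them changed). The spread of each cluster was drawn from the fitted prior and was the same in both groups. The fit recovered 66.5% of changes of 4 on the log2 scale, 2.84% of changes of 2 and 0% of changes of 1, with 5.76% of calls false. The real knockout arrays differed more from each other than the wild-type arrays did, so these shares are only a guide. The list test at the preset correlation called 100% of simulated lists of 20 independent genes shifted by 1, and gave an unadjusted p under 0.05 in 5.5% of unshifted lists. With the correlation estimated these shares were 98.5% and 0%. In the data the estimated correlations ran from -0.34 (erythroid genes) to 0.67 (cholesterol synthesis), with 0.24 for the superficial list and 0.013 for known p63 targets. The 5.5% therefore does not give the share of false calls for lists of correlated genes. The number of arrays limits the precision. The sources used here do not say whether the 2 samples of a genotype came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. No 2 arrays of a group were copies: the difference between replicates had an SD of 0.70 across clusters in the knockout and 0.44 in the wild type. Alternatives covered the normalization, filters on dim clusters, the clusters tested, the spread model, each array left out, a replicate block, the thresholds and, for lists, the correlation, the cluster per gene and shared members.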

Results

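Epithelial stem cell colonies were grown from the bladders of newborn C57BL/6J mice on 3T3 cells, a mouse fibroblast line used as a feeder layer, and colonies were picked for RNA. The design set colonies lacking p63, encoded by Trp63, against wild-type colonies, with 2 arrays in each group. p63 is a transcription factor of the p53 family found in basal cells of stratified epithelia and of the urothelium, the lining of the bladder. The comparison asks which transcripts differ in cultured bladder epithelium without p63. Across the 23332 transcript clusters, the wild-type arrays correlated at 0.98 with each other and the knockout arrays at 0.93. Correlations between a knockout and a wild-type array were 0.91 to 0.92.

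Trp63 fell 19.9-fold in the knockout colonies, from 8.99 ± 0.0046 to 4.67 ± 0.10 log2 units (mean ± SD, n = 2 per group; limma adjusted p = 0.015). The knockout level was below 5.08, the 95th percentile of olfactory receptor clusters, which serve here as silent genes. The gene-level value summarises probes along the gene, and the sources used here do not name the disrupted part. In all, 123 clusters passed the threshold, 90 of them lower and 33 higher in the knockout. A single gene name was available for 81 of the lower and 14 of the higher clusters. The smallest called change was 1.89 on the log2 scale. The calls did not hold when any 1 of the 4 arrays was left out, which leaves 1 array in a group. All 123 clusters kept the direction of their difference in each of these fits. At an unadjusted p under 0.05, 5210 clusters differed, 3414 of them higher, and the median log2 difference of all clusters was 0.12, against 0.0029 after quantile normalization. The count ran from 0 to 1007 over the alternative settings.

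**Figure D1:**
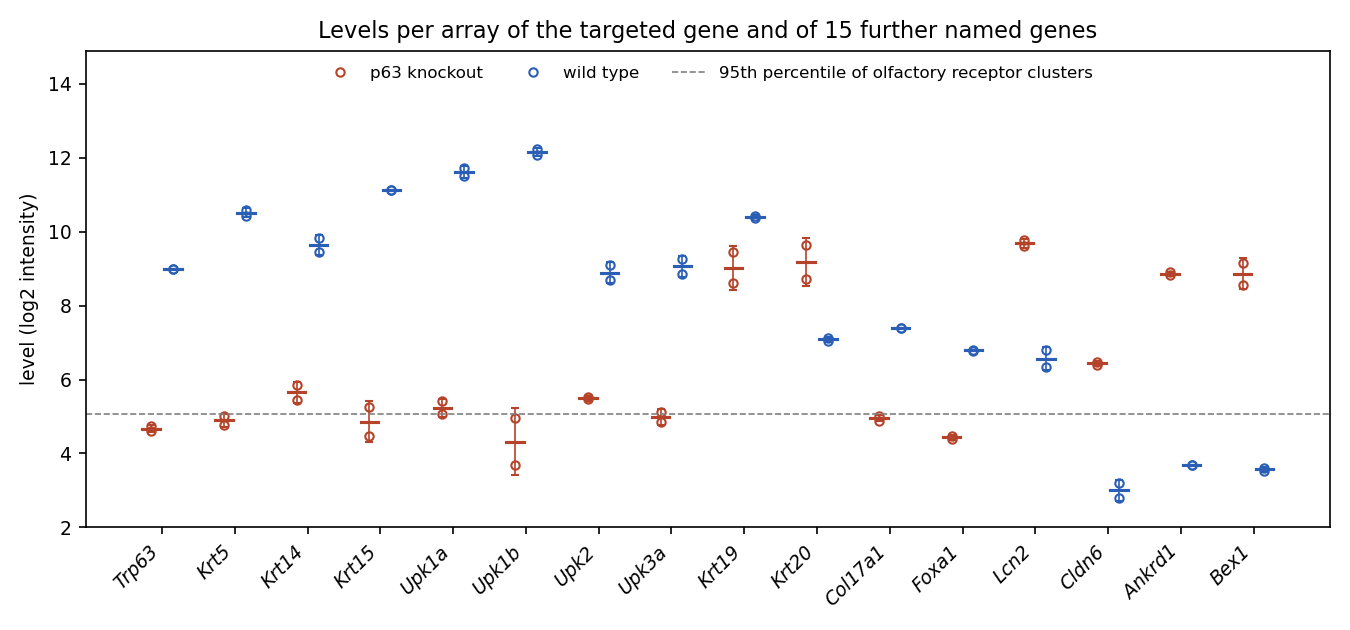
Level in log2 intensity of Trp63 and 15 further genes on each array (circles), with the group mean (bar) and SD (whiskers, n = 2 per group); the dashed line is the 95th percentile of olfactory receptor clusters, 5.08. Trp63, Krt5, Krt15, Upk1b and Upk3a have knockout means below that line and wild-type means above 8.9, while Ankrd1, Bex1 and Cldn6 show the opposite order.

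The largest decreases included genes of the differentiated urothelium. Of 17 measured superficial urothelial markers, 8 fell, 0 rose and 9 did not pass the test. Of the uroplakins, membrane proteins that coat the luminal face of the bladder, 4 fell, 229-fold for Upk1b (4.32 ± 0.90 in the knockout against 12.16 ± 0.11), 83.5-fold for Upk1a, 16.9-fold for Upk3a and 10.5-fold for Upk2 (adjusted p = 0.032, 0.015, 0.032 and 0.032). Another uroplakin gene, Upk3b, chosen after its values were seen, was at 6.71 ± 0.54 and 7.76 ± 0.15 and did not pass (adjusted p = 0.18). Snx31, a sorting nexin of superficial cells, fell 23.9-fold (adjusted p = 0.015), and Grhl3, a transcription factor of terminal epithelial differentiation, fell 8.79-fold (adjusted p = 0.032). Krt20, a keratin of superficial cells, was at 9.18 ± 0.65 in the knockout and 7.09 ± 0.07 in the wild type and did not pass (adjusted p = 0.096). The list had a median log2 difference of -2.92 (camera adjusted p = 1.3e-14; adjusted p = 0.54 with an estimated correlation). Adjusted over the list alone, 15 members were lower and 1 higher.

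Genes of basal cells fell too. Of 21 measured basal epithelial markers, 7 fell, 0 rose and 14 did not pass. Besides Trp63 these were the basal keratins Krt15 (76.7-fold), Krt5 (49.2-fold) and Krt14 (15.9-fold), Trim29 (9.71-fold), the desmosomal cadherin Dsg3 (8.97-fold) and the hemidesmosomal collagen Col17a1 (5.44-fold), with adjusted p between 0.015 and 0.033. The list's median was -0.91 (camera adjusted p = 7.8e-10; adjusted p = 0.54 with an estimated correlation), and 13 members were lower adjusted over the list alone. Without the members that other lists share, which include Krt5, Krt14 and Trp63, its median was -0.08 and its adjusted p 0.052. Among 30 measured known p63 targets, Krt5, Krt14 and Grhl3 fell, 0 rose and 27 did not pass; the median was -0.57 (camera adjusted p = 8.4e-09; adjusted p = 0.54 with an estimated correlation), with 12 lower and 1 higher adjusted over the list alone. Of 12 measured desmosome genes only Dsg3 passed, with 5 lower and 1 higher adjusted over the list alone (list median -0.50, camera adjusted p = 0.0062; adjusted p = 0.54 with an estimated correlation; adjusted p = 0.15 without shared members). In the list of 17 hemidesmosome and basement membrane genes only Col17a1 passed, 2 were lower adjusted over the list alone, and the list did not pass (median -0.21, camera adjusted p = 0.052; 0.011 without knockout replicate 2 and 0.040 without wild type replicate 2).

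Genes outside these lists were also among the 12 largest decreases. Sptssb, a small subunit of serine palmitoyltransferase, the first enzyme of sphingolipid synthesis, fell 178-fold (3.08 ± 0.26 in the knockout against 10.56 ± 0.25), and Acer2, an alkaline ceramidase, fell 43.3-fold. Adh1, an alcohol dehydrogenase that also oxidises retinol, fell 78.5-fold, and Ctse, the aspartic protease cathepsin E, fell 55.2-fold. Krt23 fell 64.8-fold, Fam25c 51.4-fold, Ly6d 38.4-fold and Ndrg2 31.3-fold, all with adjusted p between 0.015 and 0.032. The glutathione transferases Gsta3 and Gsta4 fell 9.93-fold and 5.85-fold (adjusted p = 0.038 and 0.039). They were the only 2 calls among 20 genes of retinoic acid and xenobiotic metabolism, with 5 higher and 6 lower adjusted over the list alone, a list whose median was 0.10 and mean -0.30 (camera adjusted p = 0.47). The pioneer transcription factor Foxa1 fell 5.12-fold (adjusted p = 0.034). Foxa1 and Grhl3 were the 2 calls among 27 urogenital transcription factors, which had 1 higher and 9 lower adjusted over the list alone and a median of -0.38 (camera adjusted p = 0.0078; adjusted p = 0.57 with an estimated correlation). That list lost its call without knockout replicate 2 (adjusted p = 0.098, median 0.03), without shared members (0.73) and with quantile normalization and the 25th percentile filter together (0.060). For 59 of the 81 named lower clusters the knockout mean was at or below the level of silent genes. That level was close to the median of all clusters on each array.

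Higher in the knockout colonies were Ankrd1, a nuclear and sarcomeric ankyrin-repeat protein (36.0-fold, 8.86 ± 0.06 against 3.69 ± 0.0035, adjusted p = 0.015), and Bex1 (39.3-fold, 8.87 ± 0.43 against 3.57 ± 0.06, adjusted p = 0.029). Scin, an actin-severing protein, rose 16.7-fold, the phosphatase Ptpn22 12.8-fold, the tight junction protein Cldn6 10.9-fold and Aif1l 10.4-fold (adjusted p between 0.028 and 0.034). Lcn2, an iron-siderophore carrier secreted by stressed epithelia, rose 8.67-fold, from 6.57 ± 0.31 to 9.68 ± 0.11 (adjusted p = 0.036). Efhd1 rose 6.51-fold, D630029K05Rik 5.72-fold, Scel, a cornified envelope precursor, 5.71-fold, Serpinb1b 4.87-fold and Rgs16 4.79-fold. For 10 of the 14 named higher clusters the wild-type mean was at or below the level of silent genes, which was close to each array's median.

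**Figure D2:**
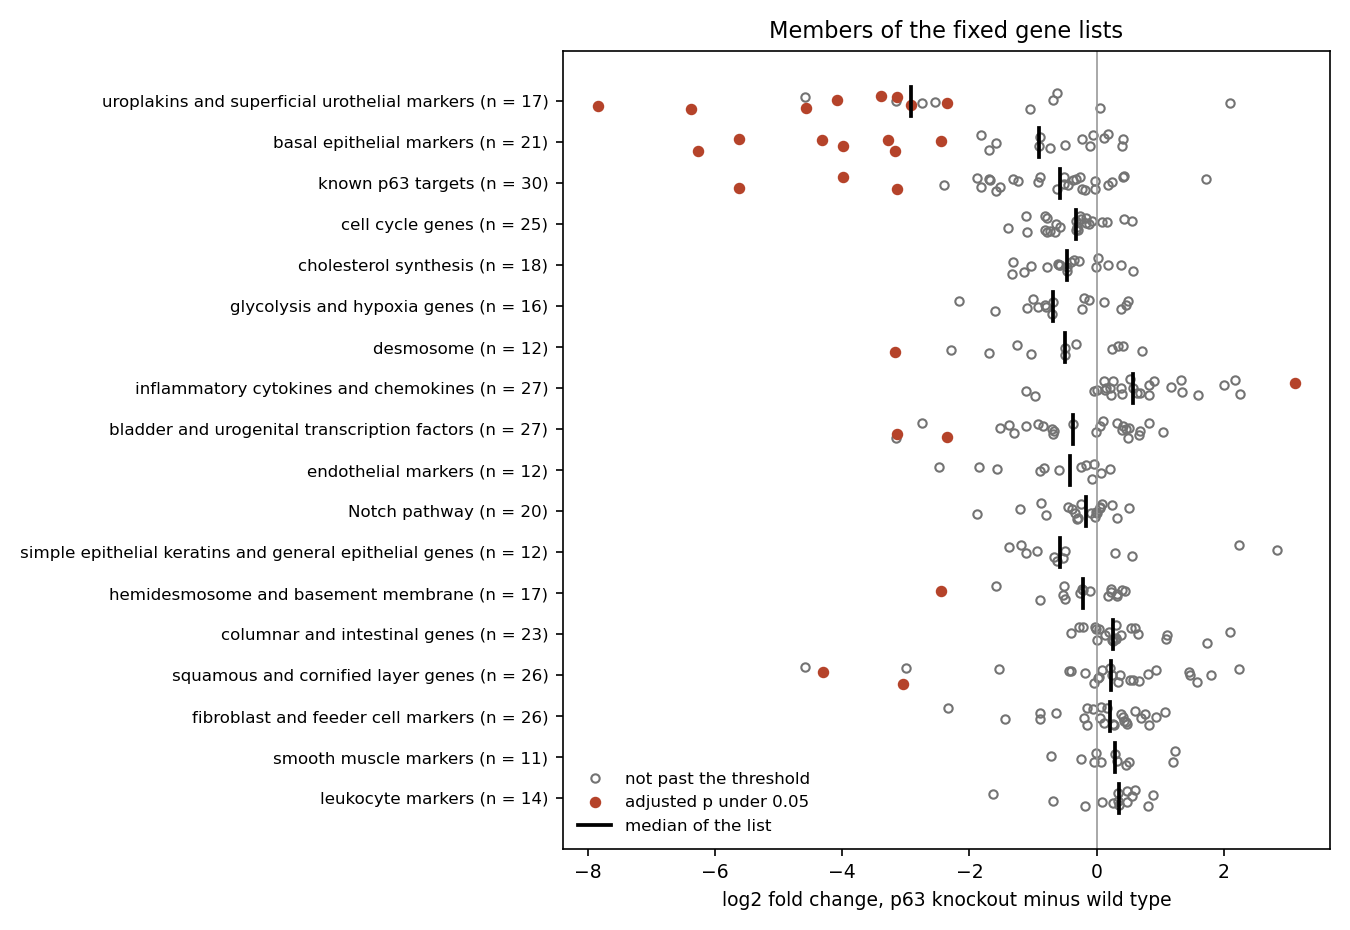
Log2 fold change, knockout minus wild type, of each measured member (circles) of 18 gene lists, with calls filled and the list median as a vertical bar. The superficial urothelial list has its median at -2.92 and 8 calls, and the fibroblast and feeder list has its median at 0.21 and 0 calls.

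Genes expressed in epithelia in general had a smaller median difference than superficial urothelial ones. None of 12 measured simple epithelial keratins and general epithelial genes passed, 2 were higher and 7 lower adjusted over the list alone, and the list's median was -0.58 (camera adjusted p = 0.022; adjusted p = 0.61 with an estimated correlation). Its call ended after quantile normalization (adjusted p = 0.078), after cyclic loess (0.076), without clusters below the 25th percentile of mean level (0.065), with that filter after quantile normalization (0.089), without knockout replicate 2 (0.21) and without shared members (0.19). Krt19 was at 9.03 ± 0.60 in the knockout and 10.41 ± 0.03 in the wild type. Prom1 (6.50 ± 1.75 against 3.67 ± 0.18) and Muc1 (6.35 ± 1.48 against 4.11 ± 0.01) varied more between the knockout arrays than between the wild-type arrays. Epcam, chosen after its values were seen, was at 8.84 ± 0.11 and 8.56 ± 0.01 (adjusted p = 0.38). Of 26 squamous and cornified layer genes, involucrin, Ivl, fell 19.6-fold and Krt13, a keratin of intermediate layers, 8.26-fold (adjusted p = 0.032 for both). Adjusted over the list alone, 4 were higher and 4 lower. That list had a median of 0.22 and a mean of -0.16 (camera adjusted p = 0.84). None of 23 columnar and intestinal genes passed, with 2 higher adjusted over the list alone (median 0.26, camera adjusted p = 0.052; adjusted p = 0.048 without wild type replicate 1 and 0.046 without clusters below the 25th percentile). The largest differences in that list were those of Krt20, Muc4 (5.51 ± 0.59 against 3.78 ± 0.25) and Car2 (6.74 ± 0.84 against 5.63 ± 0.59). Among 19 tight junction genes Cldn6 rose and Cldn8 fell 7.86-fold (adjusted p = 0.032 for both; 3 higher and 4 lower adjusted over the list alone; list adjusted p = 0.21).

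Fibroblast transcripts were measured in both groups. None of 26 fibroblast and feeder cell markers passed, and the list's median was 0.21 (camera adjusted p = 0.80). Its members were higher on knockout array 2 than on array 1 by a median of 0.56, and on wild-type array 1 than on array 2 by a median of 0.27. Its abundant members were Sparc (11.34 ± 0.55 in the knockout, 10.94 ± 0.29 in the wild type), the intermediate filament gene Vim (10.05 ± 0.48 and 9.12 ± 0.08), S100a4 (9.68 ± 0.49 and 10.56 ± 0.55) and Dcn (8.97 ± 0.07 and 10.42 ± 0.67). Endothelial markers were lower as a list (12 genes, 0 calls, median -0.42, camera adjusted p = 0.0099; adjusted p = 0.57 with an estimated correlation), a call that ended without clusters below the median of mean level (0.062). Its members were higher on wild-type array 1 than on array 2 by a median of 0.41, and the list median was -0.26 without wild type replicate 1 and -0.48 without wild type replicate 2 (camera adjusted p = 0.018 and 9.2e-05). Emcn was at 3.98 ± 0.34 and 6.46 ± 0.82, Pecam1 at 4.46 ± 0.24 and 6.30 ± 0.89, and Cdh5 at 4.13 ± 0.16 and 5.69 ± 0.61, while Egfl7 was at 5.53 ± 0.17 and 5.70 ± 0.03. None of 11 smooth muscle markers (median 0.29, adjusted p = 0.55; 1 higher adjusted over the list alone), 14 leukocyte markers (0.34, adjusted p = 0.28) or 3 erythroid genes (0.10, adjusted p = 0.78) passed. Acta2 was at 7.49 ± 0.54 and 6.25 ± 0.87, Cnn1 at 5.99 ± 0.15 and 4.80 ± 0.15, and Tagln at 5.81 ± 0.17 and 5.30 ± 0.39. The macrophage marker Cd68 was at 8.35 ± 0.32 and 7.47 ± 0.30, and Laptm5 at 4.87 ± 0.19 and 4.40 ± 0.14. All measured leukocyte markers other than Cd68 had means below the level of silent genes in both groups. The largest difference among the leukocyte markers was that of Cd79a, of B cells, lower at 2.99 ± 0.47 and 4.61 ± 0.56 (adjusted p = 0.14), and Tyrobp, chosen after its values were seen, was at 4.03 ± 0.39 and 4.71 ± 0.22. Of 9 neuronal and Schwann cell markers, Uchl1 fell 7.21-fold (adjusted p = 0.032), and the list did not pass (median -0.03, adjusted p = 0.51), with 1 higher and 2 lower adjusted over the list alone. Of the members that did not pass, Snap25 had a log2 difference of -2.16 from a wild-type level of 6.66 ± 0.26 (adjusted p = 0.094), Sox10 was at 5.30 ± 0.10 and 5.34 ± 0.17, and Stmn2, chosen after its values were seen, at 4.79 ± 0.58 and 3.16 ± 0.07 (adjusted p = 0.11).

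Several lists of cell growth and metabolism passed as lists, with no single member past the threshold. The 25 cell cycle genes had a median of -0.33 (camera adjusted p = 4.6e-04; adjusted p = 0.57 with an estimated correlation); the replication helicase genes Mcm3 and Mcm6 were at 5.12 ± 0.65 and 6.24 ± 0.36 in the knockout against 6.51 ± 0.09 and 7.36 ± 0.03. Members of this list were higher on knockout array 1 than on array 2 by a median of 0.30, and the list median was -0.66 without knockout replicate 1 and -0.24 without knockout replicate 2 (camera adjusted p = 0.011 in the latter). The 18 cholesterol synthesis genes had a median of -0.47 (camera adjusted p = 6.2e-04; adjusted p = 0.61 with an estimated correlation), with Hmgcs1 at 7.58 ± 0.39 and 8.90 ± 0.12 and 5 members lower adjusted over the list alone. Its members were higher on knockout array 1 than on array 2 by a median of 0.40, and the list median was -0.68 without knockout replicate 1 and -0.33 without knockout replicate 2 (camera adjusted p = 0.027 in the latter). The 16 glycolysis and hypoxia genes had a median of -0.69 (camera adjusted p = 0.0020; adjusted p = 0.54 with an estimated correlation), with Egln3, a hypoxia-induced prolyl hydroxylase, at 6.39 ± 0.86 and 8.56 ± 0.15 and 6 members lower adjusted over the list alone. The 20 Notch pathway genes had a median of -0.17 (camera adjusted p = 0.022; adjusted p = 0.54 with an estimated correlation), with Jag1 at 5.05 ± 0.16 and 6.94 ± 0.14 and 3 members lower adjusted over the list alone. The Notch call was lost without knockout replicate 1 (0.064), without wild type replicate 1 (0.059) and without shared members (0.11).

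Inflammatory genes were the 1 list higher in the knockout. Of 27 cytokines, chemokines and related genes, Lcn2 rose and 26 did not pass; the median was 0.57 (camera adjusted p = 0.0062; adjusted p = 0.54 with an estimated correlation), with 6 higher and 2 lower adjusted over the list alone. Lists that did not pass were ribosomal proteins (8 genes, median 0.51, camera adjusted p = 0.056), immediate early and stress genes (0.26, adjusted p = 0.065), both of which passed after quantile normalization (adjusted p = 0.024 and 0.0068), growth factor signalling (-0.25, adjusted p = 0.052; 0.048 without knockout replicate 1; 4 higher and 8 lower adjusted over the list alone) and the Hedgehog pathway (-0.14, adjusted p = 0.065; 0.033 without wild type replicate 2; 2 lower adjusted over the list alone), in which Shh, its ligand, was at 4.32 ± 0.62 and 7.13 ± 0.05 (adjusted p = 0.070). The same held for interferon response genes (0.08, adjusted p = 0.26), epithelial to mesenchymal transition (0.29, adjusted p = 0.34), p53 targets (0.20, adjusted p = 0.40) and cell cycle inhibitors (0.13, adjusted p = 0.89), with 2 higher and 2 lower, 1 lower and 1 lower in the last 3 adjusted over the list alone. Wnt genes had a median of -0.06 and a mean of 0.07 (adjusted p = 0.70; 3 higher and 1 lower adjusted over the list alone), with Wnt7a at 6.63 ± 0.35 and 3.95 ± 0.13 (adjusted p = 0.051). In tested lists given without such a count, 0 members passed adjusted over the list alone.

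Both measured Y-linked genes were low in the knockout arrays. Eif2s3y fell 22.1-fold, from 7.77 ± 0.48 to 3.30 ± 0.40 (adjusted p = 0.038), and Kdm5d was at 3.78 ± 0.0039 against 5.71 ± 0.23 (adjusted p = 0.058). The sex of the pups is not given in the sources used here, and with 2 measured members the list had no set test. Of the p53 family, Trp73, named outside the rule above, was at 4.36 ± 0.06 and 4.17 ± 0.09, and Trp53 was not analysed here. None of the 10 measured neighbours of Trp63 on its chromosome passed (median 0.21, camera adjusted p = 0.51). Cldn1, a tight junction gene, was at 8.21 ± 0.44 and 6.48 ± 0.38 (adjusted p = 0.11), Il1rap at 6.78 ± 0.14 and 6.10 ± 0.27 and P3h2 at 5.74 ± 0.34 and 6.34 ± 0.06. The log2 differences of the other 7, Lpp, Bcl6, Tprg, Cldn16, Gmnc, Ostn and Uts2b, were between -0.19 and 0.57.

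**Figure D3:**
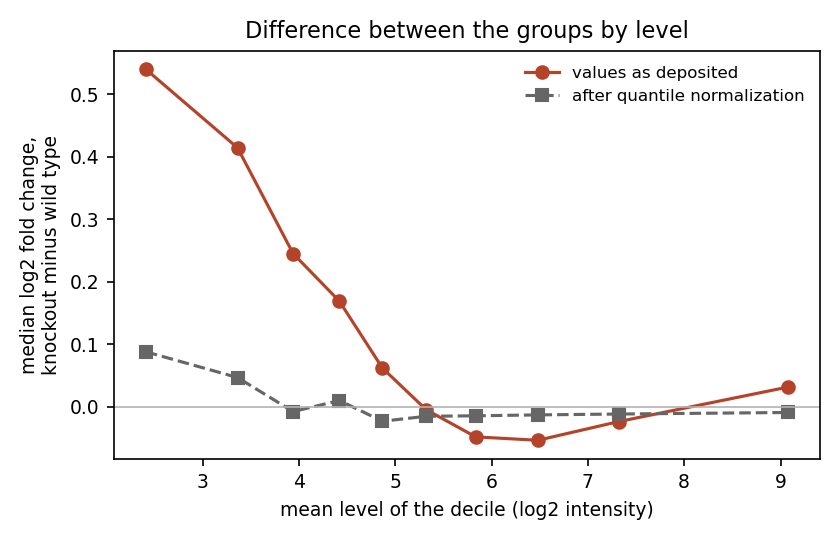
Median log2 fold change, knockout minus wild type (vertical axis), in each decile of the clusters ordered by mean level in log2 intensity (horizontal axis), as deposited and after quantile normalization. The lowest decile lies at 0.54 as deposited and at 0.09 after quantile normalization, and the highest decile at 0.03 and -0.01.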

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

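The number of calls depended on the settings. Against 123 calls (33 higher, 90 lower), limma made 105 after quantile normalization, 128 with arrays centred on their medians and 115 after cyclic loess, all within 1.5 times. Fewer dim or unnamed clusters gave more calls: 362 (126 higher, 236 lower) above the 25th percentile of mean level, 524 (186, 338) above the median and 1007 (458, 549) with 1 cluster per named gene. The last tested 14860 clusters with 3.36 prior degrees of freedom against 2.20, and the share of higher calls was 45.5% against 26.8%. A spread that follows the level (eBayes trend) gave 303 (114, 189), with the robust option 257 (95, 162), and an adjusted p under 0.10 gave 940 (509, 431). Without moderation limma's least squares fit made 0 calls, as did the fit with the replicate block, which leaves 1 residual degree of freedom. Nothing shows that the shared replicate numbers pair the samples (replicate differences of the groups correlated at 0.019 across clusters). Trp63 had an adjusted p of 0.12 with the block and 0.16 without moderation, both at -4.32. At an unadjusted p under 0.05, 4525 clusters differed with the block and 3956 without moderation. Leaving out 1 array each gave 0 calls in all 4 fits, with 2124 to 6570 clusters at an unadjusted p under 0.05, and Trp63 at -4.39 to -4.24 (adjusted p from 0.075 to 0.34). All 123 called clusters kept the direction of their difference in these 4 fits. The lone array was assumed to vary like the other group. Chosen after seeing the data, the same fits with eBayes trend made 29 calls (3 higher, 26 lower) without knockout replicate 1, 26 (5, 21) without knockout replicate 2 and 0 without either wild-type array, where Trp63 was at -4.32 and -4.31. Quantile normalization with the 25th percentile filter, also added, gave 340 (110, 230) and ended the calls of 2 lists, general epithelial genes (adjusted p = 0.089) and urogenital transcription factors (0.060). Estimating the correlation raised list p-values also where the estimate was close to the preset 0.01 or below it. For known p63 targets (estimate 0.013) camera p went from 7.9e-10 to 0.027. For inflammatory genes (estimate -0.035) it went from 0.0016 to 0.071. The size of the correlation alone therefore does not account for the lost list calls. Of the 12 lists that passed, 0 passed with an estimated correlation and 7 without shared members. Other lists gained a call: 5 with the median filter, 3 with the 25th percentile filter, 3 without wild type replicate 2, 2 each after quantile normalization, after cyclic loess, with eBayes trend (with and without the robust option), with the replicate block, without knockout replicate 1 and with the added quantile and filter setting, and 1 each without knockout replicate 2 and wild type replicate 1. Among them, ribosomal proteins (adjusted p from 0.016 to 0.041, 0.031 without wild type replicate 2) and stress genes (as low as 0.0063, and 0.028 without knockout replicate 1) gained it most often, and neuronal, p53 target and interferon lists only with the median filter (0.030, 0.030 and 0.028). The columnar list was at 0.041 with the block. Reversals were of genes and lists that never passed, with main values from -0.095 (Alas2) to 0.34 (Fcer1g), and their cause was not tested. After cyclic loess Smtn was at 0.0060 and Slc4a1 and the erythroid list at -0.020, after quantile normalization both of the latter were at -0.030 (Slc4a1 also with the 25th percentile filter), and Gmnc was at -0.26 and -0.24 after quantile and loess. With 1 array left out, values ran from -0.15 to 0.066 for Smtn, -0.27 to 0.95 for Fcer1g, -0.10 to 0.60 for Cd3e, -0.16 to 0.087 for Sox10 and -0.22 to 0.031 for Alas2. List medians then ran from 0.17 to 0.33 for squamous genes, -0.015 to 0.36 for fibroblast markers, 0.00015 to 0.36 for smooth muscle, 0.037 to 0.18 for cell cycle inhibitors and up to 0.12 for Wnt genes, with the test's direction turning in at least 1 of the 4 fits. It also turned under the 25th percentile and median filters for squamous (0.15 and -0.19) and Wnt genes (-0.058 and -0.33), and without shared members for fibroblast markers (0.12) and cell cycle inhibitors (0.10). With no detection calls, levels near those of silent genes limit how far a fold can be measured. The alternative for a linear scale did not apply, since the values are log2.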

Other observations

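Tests on sex-linked, olfactory, other-epithelium, YAP and lipid genes were chosen after the main comparison was seen but before their own values were, while the 4 tests of dilution by other cells were chosen after their values were seen, the last 2 of them after the first 2 had not decided, and the test on the sizes of the higher calls was chosen after theirs. The columnar and intestinal list, used among the other epithelia, had its values seen in the main comparison before that test. Genes in this part outside the naming rule were picked for their values. Among the calls not yet described, the urea transporter Slc14a1 had a log2 difference of -4.68, the flavin monooxygenase Fmo5 -4.44, the glucuronosyltransferase Ugt2b34 -3.26, the iron carrier Trf -2.74 and the defensin Defb1 -2.54 (limma adjusted p between 0.015 and 0.048). The highest log2 difference of any gene with its own symbol was that of Ltf, lactoferrin, a secreted iron-binding protein, at 9.69 ± 1.14 in the knockout and 3.72 ± 0.10 in the wild type (62.8-fold), which did not pass (adjusted p = 0.055).

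Among the 20 genes that differed most between the 2 knockout arrays, 16 were higher on array 1 and 4 on array 2. Prap1 was at 11.15 and 6.18 on knockout arrays 1 and 2 against 5.95 and 6.54 on the wild-type arrays, Spink8 at 9.07 and 4.94 against 2.91 and 3.14, Akr1c18 at 8.44 and 4.11 against 2.72 and 2.39, and Sprr2f at 11.73 and 8.33 against 10.44 and 10.44. Slbp was at 2.90 and 6.31 against 5.36 and 5.18, and Rps18 at 5.36 and 8.45 against 6.41 and 6.85. Over all 14860 genes the median absolute difference between replicates was 0.25 in the knockout and 0.15 in the wild type. For the inflammatory list it was 0.64 and 0.23, for the fibroblast list 0.66 and 0.41 and for cholesterol synthesis 0.40 and 0.12.

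Of the basal markers 7 of 21 fell in the knockout colonies, and of the superficial urothelial markers 8 of 17, and 4 tests asked whether fewer epithelial cells or more fibroblast or feeder RNA could account for it. The first 2 did not decide: the median log2 difference of general epithelial genes lay 2.35 above that of the superficial list, but its bootstrap 95% interval (0.54 to 3.68) reached below the stated bound of 1, and Col1a1, Col1a2 and Col3a1 had a median difference of -0.15, with a range of -0.78 to 0.48 between single arrays. The bootstrap resampled the genes of the lists, so its interval does not measure the spread between samples. The other 2 tests had bounds written once their values were known, so they carry little weight. The lower 95% bounds of all 12 general epithelial genes lay above the superficial median of -2.92, the lowest being -2.29 for Krt19. That speaks against fewer epithelial cells as the whole cause of the lower superficial markers. The same lower bounds, with a median of -1.09, lay above -2.00 for 11 of the 12 (all but Krt19). The value of -2.00 was the highest upper bound among the 7 basal calls (Col17a1). As these 7 were picked for large falls, that comparison decides nothing. The cause of the basal decreases, the 14 markers that did not pass included, stays open. Colonies of another epithelium stay open too. Of 6 lists, all but the columnar and intestinal one were without members seen beforehand. That list was retested without its largest increases, Krt20, Cldn3, Muc4 and Car2, so its lower median (0.24) decides nothing. Müllerian and uterine markers had the highest median, 0.69 over 9 genes (limma's camera p = 0.020, adjusted p = 0.10 over the 6 lists, p = 0.20 with an estimated correlation). After quantile normalization their median was 0.57, with an unadjusted camera p of 0.0082. The next lowest of the 6 lists was then at 0.062 (kidney tubule and Wolffian duct markers). An adjusted p over the 6 lists was not computed after quantile normalization. The rule set beforehand was applied only to the deposited values. Among the 9 Müllerian and uterine markers, Ltf and Pax8 (6.47 against 4.72) were highest. The hormone receptors Esr1 (4.66 against 5.07) and Pgr (4.24 against 4.99) were at -0.42 and -0.75, with both groups below the level of silent genes. A dependence of the urothelial genes on p63, the difference the design names, was not tested apart from these.

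Both Y-linked genes were low in the knockout arrays, and a candidate explanation is that these cultures came from XX pups and the wild-type cultures from XY pups. Genes that escape X inactivation had a median difference of 0.20, between the bounds set for and against it, with Kdm6a at 0.56 and Eif2s3x at 0.55 but Kdm5c at -0.14 and Ddx3x at -0.15. Loss of Y in culture was not tested. Sex-linked genes did not make up the calls: 6 of 95 called clusters with 1 gene lay on X or Y, 6.32% (exact 95% interval 2.35 to 13.2%), against 3.19% of all such clusters. Effects of sex on autosomal genes cannot be told apart from those of genotype if the sexes differed.

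Dim clusters were higher in the knockout arrays: 84.5% of the lowest decile by level had a positive difference, with a median of 0.54, against a median of 0.03 in the highest decile. Olfactory receptor clusters, expected to be silent in epithelium, were higher by a median of 0.47, with array medians of 3.35 and 3.34 against 2.89 and 2.80, which is consistent with a difference in array background or normalization. Quantile normalization lowered the log2 differences of the 33 higher calls by at most 0.40. They were then 1.48 to 5.13, against 1.89 to 5.30 as deposited, with the lowest lower 95% bound at 1.03. These calls were selected for large differences, and that bound was tested after its values were known. The bound therefore adds no weight. The decreases themselves show that the shift removed by quantile normalization made up at most 0.40 of any of these 33 differences. They argue against that shift as the whole source of the differences of these calls. Whether it carried calls past the threshold was not decided by the test set beforehand. In it 26 (78.8%) stayed past limma's threshold, just under the share set as speaking against the shift. The other 7 ended at adjusted p 0.052 to 0.073, as their differences went from between 1.89 and 3.77 (SE 0.16 to 0.33) to between 1.48 and 3.57 (SE 0.16 to 0.32). Small positive differences of dim genes, including those in the lists of columnar, prostate and airway genes, may come from this shift: the medians of the prostate and airway lists went from 0.42 and 0.19 to -0.01 and -0.05 after quantile normalization.

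Ankrd1, Ccn1 and Ccn2, textbook targets of the YAP and TAZ coactivators, were all high in the knockout arrays, with log2 differences of 5.17, 2.81 and 2.07, of which only the first passed, while Igfbp3, also counted among these targets, was at -2.40. The hypothesis that YAP and TAZ targets moved together was tested on 14 further targets, without the 6 whose values had been seen. Their median difference was 0.32 (limma's camera p = 0.081, p = 0.20 with an estimated correlation; 0.32 and p = 0.0069 after quantile normalization), which leaves the hypothesis undecided.

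Sptssb, Sptlc3, Acer2 and Fa2h, genes of sphingolipid metabolism, all fell, with log2 differences of -7.48, -4.61, -5.44 and -3.99. Of 31 measured genes in a list built around sphingolipid and very long chain lipid synthesis, 7 fell, the others being Elovl4, Elovl6 and Nipal4 (-2.63, -2.67 and -2.76). The median of all 31 was 0.04. That list was added after the main comparison, and all 7 had been seen beforehand, so their share of it is no test. The 24 genes not seen beforehand had a median of 0.16 (limma's camera adjusted p = 0.57 over the 9 lists tested in this part), but as all 7 calls were left out of that test, it cannot exclude that these genes moved together.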
